A study of Homo sapiens with 3 samples.

How the data were processed

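Poly(A)-enriched RNA from HCCLM3 cells was sequenced in 3 samples, per the labels, 1 for each group. STAR and the hg38 genome are named in the submitters' processing notes. The counting tool, the gene annotation and the strand setting are not given in the sources used here, so a gene and an overlapping or antisense partner cannot be told apart. The deposited tables, 2 per sample, hold a read count per gene symbol and a TPM value per gene symbol, per the file headers. The counts were whole numbers without normalization. The authors' TPM values summed to 884287 in the CRTC2-WT L002 table and to 960828 to 978525 in the others. That is less than TPM adds up to over all genes scaled. What accounts for the shortfall is not given in the sources used here. The ratio of count to TPM differed between tables only by a constant (largest deviation 2.29e-08 on the log2 scale over 10598 genes), so the same gene lengths were used in every table. TPM was used here only for these checks and for a check of the authors' gene lists, and every reported expression value came from the counts.

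The labels give 1 sample per group, and the tables carry names that look like sequencing lanes. They were therefore treated as repeat runs of 1 sample and never as replicates. They differed by more than sampling noise: the chi-square per degree of freedom over genes was 5.42 in Control, 7.28 in CRTC2-WT and 11.6 in CRTC2-R>A. Between the tables of a sample, 31, 38 and 69 genes with 200 or more reads differed 2-fold or more, 121 genes in all, 56 of them protein-coding. Values of those genes are described as uncertain where they are named.

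The 39691 rows of the tables held 39656 symbols, because 35 symbols appeared in 2 rows each, which were summed. Gene types and positions came from the RefSeq table of GRCh38.p14 by symbol or synonym, which matched 39236 symbols. Counts of a sample's tables were summed and scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 over the 3 samples, and separately for the L001 and the L002 tables. Log2 ratios were taken of CPM plus a pseudocount of 0.5, which understates the change of low genes. A gene was read with 1 CPM or more in any sample. It was called higher or lower if the log2 ratio of the sums, of the L001 tables and of the L002 tables each reached 1 in size with the same sign and the higher sample had at least 2 CPM. The size rule uses no p-value, and 1 sample per group allows none across conditions. Intervals of single ratios are exact binomial (Clopper-Pearson) 95% intervals and those of shares are Wilson intervals; both cover counting error only, since reads without molecular identifiers are not independent molecules. The CRTC2-R>A tables held 7253478 and 7025147 reads against 17454479 to 21451503 in the others, so its ratios are less precise.

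Named genes were the 12 with the largest log2 ratio in each direction among called genes with a mean of 5 CPM or more and an informative symbol, up to 4 such members of each described list by size of ratio, and CRTC1, CRTC2, CRTC3, CREB1, YTHDF1, YTHDF2 and YTHDF3. Not every gene that this rule selects is named. Where a list had 5 or fewer called genes, those outside this rule were named after their values were seen. The rules, the gene lists and the alternatives, save those marked otherwise, were fixed before the data were examined. Each of 39 gene lists was summarised by the median log2 ratio of its genes read. That median was placed among 10000 random lists of the same size, matched in 20 bins of mean expression, as a description of these libraries; percentiles below 2.5 or above 97.5 are called outside the range. Overlap of the comparisons with Control was set beside the overlap of independent lists, 100 simulations of unchanged samples drawn from Control, and a split of the Control tables.

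The size rule and the list percentiles were tested on simulated data with 200 changed genes and the observed spread between tables, which leaves out the spread between cultures. Of 50 genes changed 1.5-fold, 0 were called in any comparison. For CRTC2-WT against Control, 30% of 50 genes changed 2-fold, 98% of 50 changed 3-fold and 100% of 50 changed 4-fold were called among 12401 genes. For CRTC2-R>A against Control the shares were 30%, 100% and 100% among 12427 genes, and for CRTC2-WT against CRTC2-R>A they were 26%, 98% and 100% among 12419 genes. Of unchanged genes 0 were called in each. Changed genes were drawn from those at 5 CPM or more in Control, so these shares do not cover lower genes. Every gene of a sample had the same simulated spread, which left out the larger table differences of single genes. Of 200 unchanged lists, 5% to 7% fell outside the range. Those lists were drawn at random from genes simulated independently, so a share near 5% was set by the method. It gives no error rate for lists whose genes vary together.

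Alternatives were DESeq2 1.42.0 size factors, total counts, no filter or a 5 CPM filter, pseudocounts of 0.1 and 5 CPM, log2 thresholds of 0.5 and 2, single tables, sums without the agreement of tables, protein-coding genes only, unmatched random lists, and edgeR's quasi-likelihood test with each table as its own library. The last compares the deposited tables and not the conditions. Alternatives without the CRTC2-R>A L001 table, without genes whose tables disagreed, and without small RNA genes and pseudogenes were chosen after seeing the data, as were the single tables as alternatives for gene families. GC content and transcript length came from the longest GENCODE v29 transcript of each gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used for all other steps, and matplotlib 3.10.9 for figures.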

Results

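RNA was measured in HCCLM3, a human hepatocellular carcinoma line, in 3 stable cell populations. The Control sample was set against cells overexpressing CRTC2, a coactivator of the transcription factor CREB, in its wild-type form (CRTC2-WT) or as the mutant labelled CRTC2-R>A. Each group had 1 sample, so no difference between groups has a replicate check. Each sample came as 2 tables, L001 and L002, which were treated as repeat runs of that sample. The total read count was 21451503 and 17836650 in the Control tables, 19942822 and 17454479 in the CRTC2-WT tables, and 7253478 and 7025147 in the CRTC2-R>A tables. Of 39656 gene symbols, 13020 were read, 11475 of them protein-coding. Genes are called higher or lower only by a rule of size: a log2 ratio of 1 or more in size in the summed counts, the L001 tables and the L002 tables alike.

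CRTC2 itself was higher in both overexpressing samples, in both tables of each. The gene lies on chromosome 1 at 153947675 to 153958612 (GRCh38). It reached 70.2 CPM (counts scaled to library size) in Control, 587 CPM in CRTC2-WT and 351 CPM in CRTC2-R>A. The log2 ratio to Control was 3.05 in CRTC2-WT, an 8.31-fold level, and 2.31 in CRTC2-R>A, with a 95% counting interval of 2.25 to 2.39 and values of 2.28 and 2.40 in the tables. CRTC2-WT exceeded CRTC2-R>A by 0.74, which did not reach the size rule. The counts do not separate the introduced from the cell's own transcript. The related coactivators and the binding partner did not pass the rule in either comparison with Control: CRTC1 (0.28 and −0.07), CRTC3 (−0.21 and 0.04) and CREB1 (−0.32 and −0.39). YTHDF1, YTHDF2 and YTHDF3, cytoplasmic readers of N6-methyladenosine (m6A) in mRNA, stayed within 0.13 of 0, with YTHDF2 at 0.00 and −0.02 and YTHDF3 at −0.13 and −0.05.

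**Figure D1:**
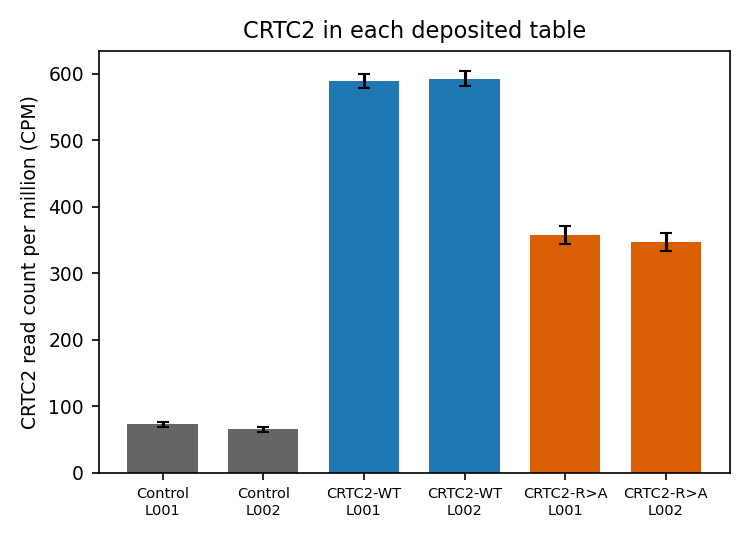
CRTC2 level in CPM (y axis) in each of the 6 deposited tables (x axis, coloured by sample); error bars are 95% exact Poisson intervals, which cover counting error only. Both Control tables lie at 73.2 and 65.6 CPM, below the CRTC2-R>A tables at 357 and 347 CPM and the CRTC2-WT tables at 589 and 593 CPM.

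The first comparison asked what differed when wild-type CRTC2 was overexpressed. In CRTC2-WT, the medians of the mitosis, DNA replication and hepatocyte marker lists lay above those of matched random lists, and the medians of the amino acid stress response, the unfolded protein response and cholesterol synthesis lay below. Most single members of these lists did not pass the rule. Apart from CRTC2 itself (3.05), CYP24A1, the vitamin D catabolising hydroxylase, led the higher genes (log2 ratio 4.82, from 3.58 to 115 CPM). Next came the proteoglycan gene SPOCK2 (4.42) and GPRIN3 (3.87). DIO2, a thyroid hormone deiodinase (3.32), and NR4A1, a nuclear receptor gene induced through CREB (3.01), stood below them. COL4A5 (2.98), TESC (2.81), PTGS2, which encodes an inducible cyclooxygenase (2.75), FGB (2.56), PLA2G4A (5.65-fold) and the mucin gene MUC13 (2.22) followed. The leading lower genes were ATF3, a stress-induced transcription factor (−4.17, from 167 to 8.81 CPM), NIBAN1 (−3.58), IGFBP1 (−3.26), BHLHA15 (−3.18), TXNIP (−3.10) and DDIT3, the stress factor CHOP (−2.77). HTR1D (−2.67), AHNAK2 (−2.56), MYOM3 (−2.45), ANKRD1 (−2.41), HERPUD1 (−2.38) and TSC22D3 (−2.28) completed the leading set.

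Among gene lists fixed beforehand, 35 mitosis and G2/M genes had a median log2 ratio of 0.93 in CRTC2-WT, at percentile 100 of 10000 random lists matched on expression. Of these, 10 were higher and 0 lower, among them NDC80 (1.34), CCNB1 (1.21), KIF2C (1.16) and AURKB (1.14). The 43 DNA replication and S phase genes had a median of 0.56 (percentile 100) although 0 passed the rule; MCM10 reached 0.97 and UHRF1 0.87. The 48 replication-dependent histone genes had a median of 0.66 (percentile 100), and 2 were higher, H1-3 (1.18) and H4C9 (1.15). Histone transcripts mostly lack poly(A) tails and are near-identical between copies, so single histone genes are uncertain. Some other RNAs without poly(A) tails also took larger shares of reads in CRTC2-WT than in Control: snoRNA genes 0.0212% and 0.0256% against 0.0103% and 0.00997%, RMRP 0.322% and 0.318% against 0.199% and 0.183%, and U6 and 5S RNA genes 0.648% and 1.01% against 0.576% and 0.630%. RN7SL genes did not (5.06% and 4.50% against 5.18% and 4.92%). The histone median may reflect how much RNA without tails each library kept, and is uncertain as a whole. Of 22 hepatocyte markers, with a median of 0.54 (percentile 100), 4 were higher and 1 was lower. The fibrinogen genes FGB (2.56) and FGA (2.83-fold), the bile acid receptor gene NR1H4 (1.88) and FOXA1 (1.02) were higher, whereas HNF4A, a liver transcription factor, was lower (−1.12). The 23 glycolysis genes had a median of 0.26 (percentile 99.9) with 0 past the rule.

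The lower side was led by 26 ATF4 and amino acid response genes, with a median of −0.83 (percentile 0) and 10 lower genes, including DDIT3, ALDH1L2 (−2.19), NUPR1 (−1.92) and DDIT4 (−1.91). Of 22 unfolded protein response genes (median −0.59, percentile 0), 4 were lower: HERPUD1 (−2.38), DNAJB9 (−1.91), SDF2L1 (−1.28) and MANF (−1.05). The 25 cholesterol synthesis genes had a median of −0.64 (percentile 0), and 4 were lower: INSIG1 (−1.41), MSMO1 (−1.40), HMGCS1 (−1.31) and HSD17B7 (−1.21). Of 22 immediate early and AP-1 genes (median −0.46, percentile 0), 5 were lower: ATF3, KLF6 (−1.80), KLF2 (−1.73), KLF4 (−1.43) and BTG2 (−1.33). The 22 p53 target genes had a median of −0.37 (percentile 0.11), and SESN2 (−1.33), which the ATF4 list also holds, and BTG2, which the immediate early list holds, were lower. Epithelial genes (17 read, median −0.33, percentile 0.74), YAP and TAZ targets (22 read, −0.29, percentile 0.85) and mesenchymal and matrix genes (26 read, −0.23, percentile 2.17) also lay low, the last not in the L001 tables alone (−0.11, percentile 17.3). The matrix list went both ways: LAMB3 (−1.97) and SNAI2 (−1.13) were among the lower genes, and TGFBI (1.82), THBS1 (1.37) and LOXL2 (1.09) were higher.

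In all, 174 genes were higher and 234 lower in CRTC2-WT than in Control, 145 and 219 of them protein-coding. In simulated unchanged samples, 0 genes passed the same rule on average, but that covers counting error only and not the spread between cultures. Among markers of other cells, 5 endothelial genes had a median of 0.72 (percentile 98.7), with ESAM at 0.72, PECAM1 at 0.39 and LYVE1 higher (1.11), and the leukocyte list rested on 2 genes (1.17, percentile 98.8), of which CD79A was higher (1.28). In the L001 tables alone the endothelial median was 0.56 (percentile 93.8), and in the L002 tables alone the leukocyte median was 0.87 (percentile 92.4). Fibroblast markers (2 genes, −0.62, percentile 6.91) and markers of a kidney packaging line (4 genes, −0.11, percentile 36.1) stayed inside the range.

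The second comparison asked the same of the CRTC2-R>A protein. The medians of the stress and cholesterol lists again lay below 0, and the medians of the mitosis and DNA replication lists lay above 0 with 0 of their genes past the rule. Of the 113 higher genes, 56 were small RNA genes or pseudogenes. Apart from CRTC2 itself (2.31), the leading higher protein-coding genes were FAM167A (4.04), MUC13 (2.27), TNS4 (1.98), NR4A1 (1.87) and ANPEP, an aminopeptidase gene (1.81). The small nuclear RNA genes RNU6-1 (3.30), RNU6-7 (3.21), RNU4-2 (2.77), RNU6ATAC (2.47), RNU4-1 (2.39) and RNVU1-31 (1.84) stood among them. Apart from RNVU1-31 their values differed at least 2-fold between the CRTC2-R>A tables, and these RNAs share reads with near-identical copies. The leading lower genes included NIBAN1 (−2.34), PHGDH, an enzyme of serine synthesis (−2.33), HID1 (−2.28), ATF3 (−2.22), SPANXC (−2.21), DDIT4 (−2.10), STRA6 (−2.10), BHLHA15 (−2.06) and TSC22D3 (−2.04). H19 (−4.30), CUTA (−2.80) and GTPBP6 (−2.09), all uncertain, ranked there too. The H19 log2 ratio was −6.43 in the L001 and −2.02 in the L002 tables, and GTPBP6 disagreed between tables in CRTC2-WT. CUTA lies at the major histocompatibility complex, where few reads were counted.

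The 26 ATF4 and amino acid response genes had a median of −0.75 (percentile 0) in CRTC2-R>A, and 8 were lower, with PHGDH (−2.33), DDIT4 (−2.10), DDIT3 (−1.94) and ALDH1L2 (−1.87) in front. Unfolded protein response genes had a median of −0.92 (percentile 0) and 6 lower genes, among them HERPUD1 (−1.58), MANF (−1.44), DNAJB9 (−1.44) and PDIA4 (−1.30). Cholesterol synthesis genes had a median of −0.72 (percentile 0), and HSD17B7 (−1.91), INSIG1 (−1.52), MVD (−1.44) and SQLE (−1.43) were the 4 lower ones. Immediate early genes (median −0.43, percentile 0) had 2 lower genes, ATF3 and KLF6 (−1.10), and p53 targets (−0.33, percentile 0) had 1, SESN2 (−1.25). Epithelial genes (−0.31, percentile 0.705) and YAP and TAZ targets (−0.22, percentile 1.75) lay low with 0 genes past the rule. Without the CRTC2-R>A L001 table the YAP and TAZ median was −0.13 (percentile 15.2). Mitosis genes lay at 0.44 (percentile 100) and DNA replication genes at 0.16 (percentile 100), with 0 genes past the rule in each; AURKA, a mitotic kinase, reached 1.04. Histones lay at 0.34 (percentile 100) with 0 past the rule, or 0.25 (percentile 100) without the CRTC2-R>A L001 table. That median is uncertain as well: H3C14, H4C14 and H4C15 differed at least 2-fold between the CRTC2-R>A tables, and U6 and 5S RNA genes took their largest share in that sample. NRF2 targets (0.07, percentile 100), fatty acid oxidation genes (0.19, percentile 99.7) and MAPK output genes (0.10, percentile 99.4) lay just above the range. Against random lists not matched on expression, NRF2 targets (percentile 93.0) and MAPK output genes (percentile 93.2) fell inside it. Among MAPK output genes, SPRED3 (1.40) was the 1 higher gene. Hepatocyte markers (−0.03, percentile 29.9, or 0.03 without the L001 table) stayed inside the range, with ALB, the albumin gene, lower (−1.42) and FOXA3 higher (1.39).

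In all, 113 genes were higher and 104 lower in CRTC2-R>A than in Control, 50 and 95 of them protein-coding. The share of reads on U6 and 5S RNA genes was 2.76% (95% Wilson interval 2.75 to 2.77) in the CRTC2-R>A L001 table and 1.12% in its L002 table, against 0.576% and 0.630% in Control and 0.648% and 1.01% in CRTC2-WT. Without the CRTC2-R>A L001 table, an alternative chosen after seeing the data that also drops a repeat from the rule, 148 genes were higher and 186 lower, and the ATF4, unfolded protein response and cholesterol synthesis medians were −0.78, −0.90 and −0.84. On the sums of both tables alone, the numbers were 254 and 202.

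The third comparison set the 2 proteins against each other. CRTC2 stood at 587 CPM in CRTC2-WT and 351 CPM in CRTC2-R>A, so the form of the protein and its level cannot be told apart. The medians of the mitosis, DNA replication and hepatocyte marker lists lay above 0, and those of interferon-stimulated genes and of growth factor and receptor genes lay below 0, with few or none of the members past the rule. Higher in CRTC2-WT were SPOCK2 (4.53), CYP24A1 (4.51), GPRIN3 (3.70), CALB2 (3.13), RARRES1 (3.13), the keratin gene KRT7 (2.97), STRA6, a retinol transporter gene (2.88), the transglutaminase gene TGM2 (2.83), CP, which encodes ceruloplasmin (2.75), PALMD (2.57), IGFBP6 (2.43) and TMC5 (2.43). Among the genes lower in CRTC2-WT were ANPEP (−2.57), CREB3L3, a liver transcription factor gene (−2.42), RAB27B (−2.36), ANKRD40CL (−2.25), ABR (−2.22), HTR1D (−2.19), FAXDC2 (−2.08), ATF3 (−1.94) and CDA (−1.93). RNU6-1 (−3.11) ranked there as well, with disagreeing CRTC2-R>A tables, and so did U2AF1 (−2.24), whose tables disagreed only in Control.

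Mitosis genes differed by a median of 0.44 (percentile 100), DNA replication genes by 0.44 (percentile 100) and histones, uncertain here too, by 0.29 (percentile 100), with 0 genes past the rule in each. Hepatocyte markers differed by 0.50 (percentile 100), with ALB (2.29), FGB (1.95), NR1H4 (1.53) and FOXA1 (2.29-fold) the 4 higher genes. Oncofetal and progenitor markers differed by 0.38 (percentile 99.9); KRT7 was higher, ANPEP lower, and H19 (2.41) uncertain. Without the CRTC2-R>A L001 table that median was 0.25 (percentile 98.4). Cholesterol synthesis genes (0.28, percentile 99.9) and unfolded protein response genes (0.21, percentile 98.3) had medians above the range. ATF4 genes did not stand apart (−0.07, percentile 11.9). CBS (2.13) was the 1 higher gene of the ATF4 list. It is described as uncertain because its tables disagreed in Control (207 and 64 reads), although Control does not enter this ratio. NF-kB and cytokine genes (0.25, percentile 98.9) had 3 higher genes, CXCL2 (1.44), CXCL8 (1.31) and PTGS2 (1.29). TGF-beta targets (0.24, percentile 97.6) had 1, TGFBI (1.73), and translation factors (0.23, percentile 99.3) had 0, with EIF3A at 0.95 and EIF5B at 0.80. On the lower side, interferon-stimulated genes had a median of −0.30 (percentile 0.24) and 3 lower genes, IFIT2 (−1.93), OASL (−1.88) and IFIT1 (−1.84). Receptors targeted by lenvatinib, a multikinase inhibitor, and growth factor genes had a median of −0.29 (percentile 0.58); the ligand genes EREG (−1.53) and TGFA (−1.41) and the receptor gene FGFR1 (−1.23) were the 3 lower genes. Of these lists, 5 fell inside the range without the CRTC2-R>A L001 table: unfolded protein response (0.13, percentile 93.6), NF-kB and cytokine (0.19, percentile 96.8), TGF-beta (0.13, percentile 89.0), translation factor (0.12, percentile 91.5) and lenvatinib target and growth factor genes (−0.22, percentile 2.70). Interferon-stimulated genes did so in the L001 tables alone (−0.22, percentile 3.99). Markers of other cells rested on few genes. The endothelial median was 0.41 (percentile 94.9), or 0.99 (percentile 99.7) without the CRTC2-R>A L001 table. The leukocyte median was 0.98 (percentile 97.4), or 1.64 (percentile 99.4) in the L001 tables alone. Fibroblast markers (−0.34, percentile 25.1) and kidney packaging line markers (0.09, percentile 62.3) stayed inside the range.

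In all, 123 genes were higher and 124 lower in CRTC2-WT than in CRTC2-R>A. Without the CRTC2-R>A L001 table the numbers were 214 and 189, and on the sums alone they were 209 and 312. Between CRTC2-R>A tables the SD of the log2 ratio over well-counted genes was 0.22, against 0.09 from counting alone, and it was 0.15 in Control and 0.16 in CRTC2-WT.

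Both overexpressing samples were also read against each other's changes. The 22 genes higher in both than in Control included CRTC2, NR4A1, PTGS2, MUC13, COL4A5, DIO2 and TESC. The 54 genes lower in both included ATF3, DDIT3, DDIT4, HERPUD1, DNAJB9, MANF, INSIG1, IGFBP1 and LAMB3. Lists drawn independently would share 1.51 and 1.87 genes, and simulated unchanged samples shared 0 and 0. With 0 and 0.02 genes past the rule on average, the simulated samples could share none, so those counts are no measure of overlap without change. On sums alone 56 and 96 genes were shared. With 1 Control table given to each comparison, 65 and 81 were shared in one assignment and 59 and 76 in the other. The covariance of the log2 ratios across genes was 0.121, against 0.00513 in simulated unchanged samples, and 0.0983 and 0.0928 with the Control tables split. The correlation across genes, which are not independent replicates, was 0.48 (0.36 simulated). The simulation held counting error only, without the spread between tables or cultures. Its covariance and correlation are therefore no measure of overlap without change either. Part of the overlap may come from the shared Control sample, since both Control tables belong to that 1 sample. Whether they stem from the same culture or library is not given in the sources used here. KRT7 was the 1 gene that passed the rule in opposite directions.

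**Figure D2:**
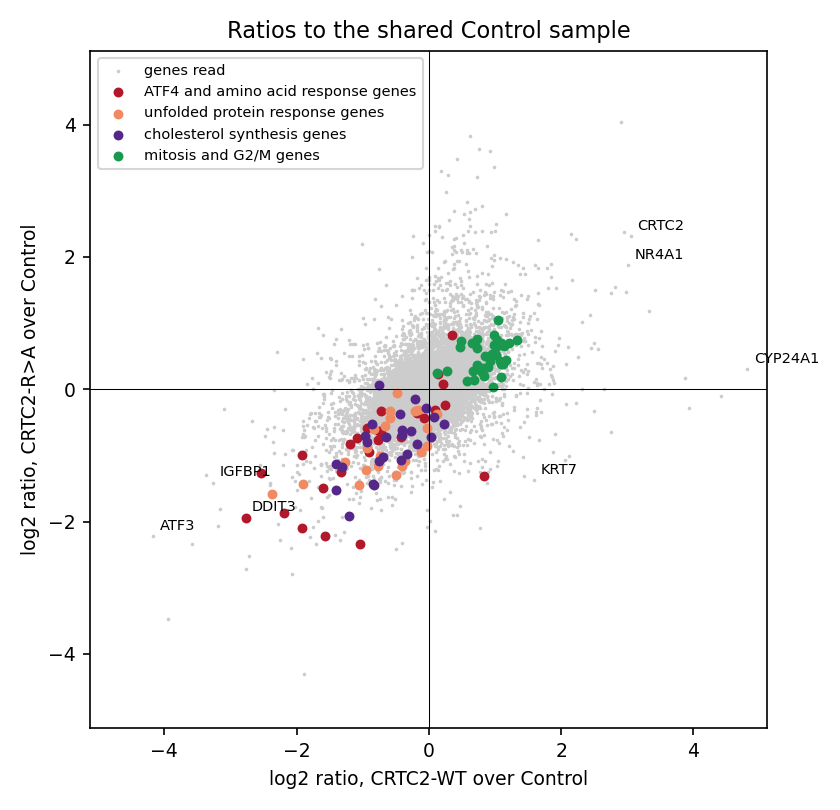
Log2 ratio of each gene read in CRTC2-WT over Control (x axis) and CRTC2-R>A over Control (y axis), with 4 gene lists coloured; each point is a gene and both axes share the Control sample. The ATF4 list (medians −0.83 and −0.75) lies at the lower left and the mitosis list (0.93 and 0.44) at the upper right.

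The authors' deposited table listed 363 genes under UP and 370 under DOWN without a stated comparison or rule. Of those read here, 168 of 307 UP genes were higher and 224 of 346 DOWN genes were lower in CRTC2-WT, and 32 and 56 passed the rule in CRTC2-R>A. For all 363 and all 370 genes, the TPM values of the CRTC2-WT tables did not overlap those of the Control tables. The lists thus follow CRTC2-WT against Control, so their smaller counts in CRTC2-R>A may partly reflect that choice. The lists were chosen on these samples, so they are not independent evidence of direction.

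The list of CREB and CRTC target genes did not stand apart as a whole. Its 28 genes had medians of −0.15 (percentile 10.5) in CRTC2-WT and −0.09 (percentile 21.9) in CRTC2-R>A, since members went both ways. NR4A1 (3.01 and 1.87) was higher in both, SIK1 (1.13) in CRTC2-WT and NR4A3 (1.22) in CRTC2-R>A. ATF3 (−4.17 and −2.22) and MAFF (−1.40 and −1.24) were lower in both, KLF4 (−1.43) and the clock gene PER1 (−1.36) in CRTC2-WT. The 24 m6A writers, erasers and readers had medians of 0.09 (percentile 94.9) and −0.03 (percentile 83.5) with 0 past the rule; HNRNPA2B1 stood at 0.52 and METTL3 at 0.44 in CRTC2-WT. YTHDC1 was uncertain because its tables disagreed. Against Control, translation factors lay at 0.03 and −0.20, lenvatinib target and growth factor genes at −0.14 and −0.04, interferon-stimulated genes at −0.21 and 0.07, oncofetal markers at 0.11 and −0.11, and NF-kB and cytokine genes at 0.03 and −0.12. Without the CRTC2-R>A L001 table, interferon-stimulated genes in CRTC2-R>A moved outside the range (0.20, percentile 99.2), and the medians of oncofetal markers (0.02), lenvatinib target and growth factor genes (0.02) and m6A genes (0.00) changed sign inside it.

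The remaining lists stayed inside the range in all 3 comparisons as computed from both tables, though not under every alternative. Their medians in CRTC2-WT and CRTC2-R>A were −0.02 and −0.21 for ribosomal proteins, −0.06 and −0.05 for nuclear-encoded respiratory chain subunits, −0.12 and −0.20 for gluconeogenesis genes (0.01 in CRTC2-R>A without its L001 table), −0.21 and −0.12 for hypoxia genes, and −0.06 and −0.11 for fatty acid synthesis genes. They were 0.08 and 0.12 for Wnt targets, 0.11 and −0.07 for drug transport and metabolism genes, −0.02 and −0.09 for autophagy and lysosome genes, and 0.03 and −0.05 for P-body and mRNA decay genes. Hypoxia genes in CRTC2-R>A left the range in the L001 tables alone (−0.25, percentile 1.62). Without that sample's L001 table their median was −0.02. Single members of these lists passed the rule in CRTC2-WT, among them TBX3 (1.62), ACSS2 (−1.18) and the autophagy genes WIPI1 (−1.49) and MAP1LC3B (−1.32). Of 20 antigen presentation genes only 4 were read (−0.50 and −0.21), and the 13 mitochondrially encoded protein genes were listed at 0 reads in all 6 tables. Many of the antigen presentation genes, such as the HLA genes and TAPBP, lie in the histocompatibility region, where few reads were counted. Neither absence is evidence that the genes were not expressed. Whether any gene list is shifted beyond the spread between cultures was not testable with 1 sample per group.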

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

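Of the tests in this part, those on GC content and length, on depth and on the histocompatibility region were fixed before their results were seen, and the others were chosen afterwards.

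KRT7, a keratin gene on chromosome 12 at 52233243 to 52255853, passed the size rule in opposite directions against the same Control. It stood at 21.1 CPM in Control, 64.9 CPM in CRTC2-WT (log2 ratio 1.60, with 1.72 and 1.49 by table) and 7.85 CPM in CRTC2-R>A (−1.37, with −1.49 and −1.24 by table). The overexpressing samples differed by 2.97 on the log2 scale, and with 1 sample each this difference was not tested.

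The medians of the ATF4, unfolded protein response and cholesterol synthesis lists lay below 0 in both overexpressing samples. After a smooth correction for GC content and transcript length, the least negative of the 6 medians was −0.56, which argues against that bias as the whole cause. After thinning Control and CRTC2-WT to the CRTC2-R>A depth, the least negative median was −0.59. Thinning keeps the expected ratio of well-counted genes, so it could not decide on depth. CRTC2-WT had 37397301 reads against 39288153 in Control. Its medians were −0.83, −0.59 and −0.64, which argues against depth as the cause in that sample. A stress state of the Control cells, such as crowding or spent medium, may have raised these genes there and stays open. The overexpressing samples differed from each other by at most 0.28 (cholesterol synthesis), less than each differed from Control. That median (percentile 99.9) and the unfolded protein response median (0.21, percentile 98.3) lay outside the range of random lists. The latter fell inside it in the L001 tables alone (0.19, percentile 89.2) and in the L002 tables alone (0.13, percentile 92.9). It also did so without the CRTC2-R>A L001 table (0.13). With a single Control sample, a stress state of the Control cells and an effect common to both CRTC2 proteins cannot be told apart.

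U6 and 5S RNA genes took a larger share of reads in CRTC2-R>A than in either other sample, and so did RMRP (0.488% and 0.392%, against at most 0.322%). The snoRNA genes (0.0241% and 0.0169%) exceeded Control but were mixed against CRTC2-WT (0.0212% and 0.0256%). RN7SL genes (4.27% and 4.87%) lay below Control (5.18% and 4.92%) and were mixed against CRTC2-WT (5.06% and 4.50%). The U6 and 5S share differed 2.46-fold between the CRTC2-R>A tables, which hold the same sample. This is in line with a library preparation that kept more small or unselected RNA, if the tables stem from separate preparations, which the sources used here do not state. An effect of the R>A protein stays open: the lower CRTC2-R>A share exceeded the highest of the other samples 1.11-fold, but the CRTC2-WT shares differed 1.56-fold between runs, so the effect and the preparation cannot be told apart.

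Genes such as H19 (2274 and 426 reads) and YTHDC1 (331 and 25 reads) differed between the tables of Control. Counting alone would give 0.000942 such differences of 2-fold or more over all genes of 200 or more reads, against 138 observed, which argues against sampling of few reads, although these genes were counted less deeply (a median of 417 reads in Control against 1533 for all genes of 200 or more reads). Reads may instead be lost where a genome with alternate contigs holds a region more than once. The 28 genes of the histocompatibility region that every cell uses had a median of 0.0871 CPM, against 30.5 CPM for protein-coding genes read. These 28 genes are not among those whose tables disagreed, but this was largely fixed in advance. They had at most 259 reads over all 6 tables (BAG6), and a gene needed 200 or more in a sample to be compared. DHX16, also in that region, did differ in Control (299 and 2 reads). The low counts of the 28 genes do not show why H19, YTHDC1 or the others differed. Of the 121 genes that differed in any sample, 59 were small RNA genes or pseudogenes. Why a loss of reads would differ between tables was not tested, and no biological explanation was tested.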

How the results depend on the processing

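Among the alternatives, those without the CRTC2-R>A L001 table, without genes whose tables disagreed and without small RNA genes and pseudogenes were chosen after seeing the data. No paired analysis was possible because each group had 1 sample. Counts of called genes are given for CRTC2-WT against Control, CRTC2-R>A against Control and CRTC2-WT against CRTC2-R>A, in that order, with 408, 217 and 247 as reported. They were 170, 67 and 86 with a pseudocount of 5 CPM, 1991, 1066 and 1378 at a log2 threshold of 0.5, and 45, 18 and 32 at a threshold of 2. They were 705, 758 and 924 in the L001 tables alone and 768, 511 and 599 in the L002 tables alone, where no agreement was required. On sums only, the count was 456 for CRTC2-R>A and 521 for CRTC2-WT against CRTC2-R>A. Without the CRTC2-R>A L001 table these were 334 and 403. With each table as its own library, edgeR called 4226, 2419 and 3503 genes at an adjusted p of 0.05, of which 351, 238 and 204 were at least 2-fold higher and 362, 170 and 302 at least 2-fold lower. All other totals stayed within 1.5 times the reported ones, but their splits moved. In CRTC2-R>A against Control, 113 higher and 104 lower genes as reported were 67 and 85 with a 5 CPM minimum, 138 and 85 with total counts, 95 and 102 without genes whose tables disagreed, and 57 and 101 without small RNA genes and pseudogenes. In CRTC2-WT against CRTC2-R>A, 123 and 124 were 105 and 152 with total counts. The 76 genes shared in direction were 26 with a pseudocount of 5 CPM, 181 in the L001 tables and 190 in the L002 tables.

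The CRTC2 log2 ratio of 3.05 was 3.11 with total counts, 2.98 with a pseudocount of 5 CPM and 3.17 in the L002 tables. That of 2.31 in CRTC2-R>A was 2.44, 2.24 and 2.40, and that of 0.74 between the proteins was 0.68 with total counts. Total counts moved the median of all genes in CRTC2-R>A against Control from −0.04 to 0.08. The number of lists outside the range, 15, 13 and 12 as reported, ranged over 13 to 16, 13 to 16 and 9 to 14. Of the lists outside the range, 12, 10 and 6 were so under every alternative. The sign changed in 0 of 964 alternative values of called named genes, 0 of 265 of list medians outside the range and 62 of 495 of those inside it. Thinning Control and CRTC2-WT to the CRTC2-R>A depth gave 441, 234 and 258 called genes. The cause of the other shifts was not tested.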

Other observations

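Some gene families were looked at after the values were seen, 11 in all, by symbol. Several share members with the gene lists, so their medians partly repeat list results. HSPA5, DNAJB9, DNAJC3 and DNAJB11 are in the unfolded protein response list, and KIF2C, KIF11, KIF20A and KIF23 are in the mitosis list. FGA, FGB, FGG, SERPINA1 and several apolipoprotein genes are in the hepatocyte list. KRT7 and KRT19 are in the oncofetal list, and KRT8, KRT18 and KRT19 are in the epithelial list. Genes of calcium-binding S100 proteins lay low in CRTC2-WT. The 9 read had a median log2 ratio of −0.82 against Control (percentile 0), and S100A3 (−1.73), S100A10 (−1.45), S100A2 (−1.36) and S100A11 (−1.24) passed the size rule. In CRTC2-R>A the median was −0.33 (percentile 2.79) and 0 passed it, with −0.30 (percentile 12.1) in the L001 tables alone and −0.37 (percentile 0.16) in the L002 tables alone. Annexins, membrane-binding proteins of which some pair with S100 proteins, had medians of −0.58 (percentile 0.03) and −0.45 (percentile 0.27) over 9 genes, and ANXA3 was lower in both (−2.02 and −1.78). In the L001 tables alone the annexin median in CRTC2-R>A was −0.37 (percentile 4.17), inside the range. The metallothionein gene MT2A was lower in both as well (−1.91 and −1.44).

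Cytosolic aminoacyl-tRNA synthetases were below 0 in 18 of 20 genes in CRTC2-R>A (median −0.45, percentile 0), with CARS1 lower (−1.63). In CRTC2-WT their median was −0.17 (percentile 11.5), again with CARS1 lower (−1.04). VARS1 lies in the histocompatibility region and is uncertain. Heat shock and DNAJ genes, 51 in all, had medians of −0.20 (percentile 0.65) and −0.35 (percentile 0), and HSPA5, the chaperone BiP, was lower in CRTC2-R>A (−1.16). Kinesins, microtubule motors, had a median of 0.35 in CRTC2-WT against CRTC2-R>A over 34 genes (percentile 100), with 0 past the rule. Without the CRTC2-R>A L001 table that median was 0.28 (percentile 100).

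Over 12 keratin genes the median was −0.22 in CRTC2-WT (percentile 7.98, with 8 genes below 0) and −0.56 in CRTC2-R>A (percentile 0.01, or −0.34 at percentile 0.75 in the L002 tables alone). The CRTC2-WT median was −0.33 (percentile 2.17) in the L001 tables alone and −0.0034 (percentile 44.9) in the L002 tables alone. KRT20 was lower in both (−1.68 and −1.48). KRT7 (1.60), KRT83 (2.23) and KRT86 (1.62) were higher in CRTC2-WT, but KRT83 and KRT86 have near-identical copies and can share reads. Between the overexpressing samples the median was 0.47 (percentile 99.9), but 0.25 (percentile 93.9) in the L002 tables alone and 0.28 (percentile 96.3) without the CRTC2-R>A L001 table, both inside the range. The single tables and the sums without that table were chosen as alternatives for these families after seeing the data.

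Fibrinogen, serpin and apolipoprotein genes lay just outside the range in CRTC2-WT (0.19, percentile 97.7), though not in the L001 tables alone (0.20, percentile 96.6). APOL1 (1.45) and SERPINB9 (1.39) were higher beside the fibrinogen genes. Against CRTC2-R>A the median was 0.25 (percentile 99.5) with 3 higher genes, but 0.02 (percentile 57.9) in the L001 tables alone and 0.14 (percentile 91.7) in the L002 tables alone. Collagens (0.15, percentile 87.5), integrins (0.16, percentile 94.1) and solute carriers (−0.07, percentile 15.8) stayed inside the range in CRTC2-WT against Control.

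RN7SL genes, the RNA of the signal recognition particle, took 4.27% to 5.18% of reads in all 6 tables, although the RNA had been selected for poly(A) tails. The snoRNA genes took 0.0103% and 0.00997% in Control, 0.0212% and 0.0256% in CRTC2-WT, and 0.0241% and 0.0169% in CRTC2-R>A. RMRP took 0.199% and 0.183% of reads in Control, 0.322% and 0.318% in CRTC2-WT, and 0.488% and 0.392% in CRTC2-R>A.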
